A study of Mus musculus with 15 samples.

How the data were processed

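Small RNA was sequenced from 15 mouse libraries in 6 groups: wild type (WT) and miR-302 knockout (KO) at embryonic days 7.5, 8.5 and 9.5. Per the labels, the E7.5 samples were whole embryos, the E8.5 samples were cells sorted for a Wnt1-Cre lineage reporter, and the E9.5 samples were cells sorted for Sox10. Wnt1-Cre marks the dorsal neural tube and the neural crest that leaves it, and Sox10 marks migrating neural crest. Stage and cell source therefore change together and cannot be told apart. Per the labels' protocols, RNA was isolated with a miRNeasy or Trizol-LS method and libraries were made with the NEXTflex Small RNA-seq kit v3. No label says that the samples of a group were separate litters, so p-values measure only the spread between these samples, which may in part be technical.

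Reads were aligned with STAR 2.7.0f to mm10 after quality checks with FastQC 0.11.5, per the submitters' processing notes. The counting tool and the tool behind the size factors are not given in the sources used here. The signal analysed here is the deposited table of normalized counts, in which the authors had divided the read count of each hairpin by 1 size factor per library. Each deposited value above 0 was a whole multiple of what 1 read was worth in its library (100% of 6086 values, within 0.001), so reads and depth could be recovered. Median-of-ratios factors computed from these 15 libraries were 0.904 to 1.15 times the authors' deposited factors, once both were scaled to the same geometric mean. The table listed 3337 entries. All 2108 entries named for a mature arm were 0 in all 15 libraries, so the 5' and 3' arms of a hairpin could not be separated. The other 1229 entries named hairpins, 3 of them repeated names, which left 1226 hairpins, 934 of them with a value above 0. The authors' deposited cluster table, whose only value is the number of the Mfuzz cluster of each miRNA, is an other unit and was used only to describe the WT stages. In the authors' deposited sheets 1 further column of per-library values matched no sample of the series and was not used. Sheets that hold means, fold changes or subsets of the same table were not used either.

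Depth ran from 1706 to 323389 reads per library, a 190-fold range, with 1336573 reads in all. The worth of 1 read ran from 0.147 normalized counts in E9.5 WT replicate 1 to 19.3 in E8.5 KO replicate 3. Each pair of replicates differed by more than sampling noise (chi-square per degree of freedom 3.04 to 207), so none was merged. Tested hairpins had at least 10 normalized counts in at least 2 libraries. This left 299 hairpins that held 98.5% to 99.6% of each library's reads. Of these, 54 belong to 26 families of numbered copies, such as let-7a-1 and let-7a-2, that share reads, so they are not independent measurements.

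The test was limma 3.58.1 (lmFit, eBayes with trend, two-sided) in R 4.3.3 on log2(normalized count + 1). All 15 libraries entered 1 model with 6 group means, and Benjamini-Hochberg adjustment ran over the 299 hairpins with a threshold of 0.05. Fold changes are on that scale and understate the change of hairpins near 0. An F test of the interaction contrasts asked whether the KO effect differed between stages. The design, the filter, the lists and the rule for named hairpins were fixed before the data were examined. The rule named each miR-302/367 hairpin. It also named, per comparison, the 10 highest and 10 lowest log2 fold changes among hairpins past the threshold with no overlap between groups and a mean of at least 100 normalized counts in the higher group. Up to 4 members of each list with the highest mean over all libraries were named as well. For the interaction, it took hairpins past the threshold with a mean of at least 100 over all libraries. Other hairpins are named only where a count was small, and were chosen after their values were seen: mir-297a-3, mir-297a-4, mir-297b, mir-297c, mir-1953, mir-3081, mir-871, mir-219a-2, mir-5110, mir-6236 and the chromosome X hairpins.

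There were 18 lists, 8 of them for other cell types or layers that the embryo or the gate could hold: the clusters of miR-302 with miR-367, miR-290-295, miR-17-92, miR-182 with miR-183 and miR-96, miR-322 with miR-503, Dlk1-Dio3 and Sfmbt2, the let-7 family, the family of miR-99, miR-100 and miR-125, the family of miR-34 and miR-449, the Hox-cluster miRNAs, and neural, epithelial, muscle, blood, vascular, mesenchymal, and endoderm and liver miRNAs. The Sfmbt2 list counts among the 8. Each list with at least 3 tested members went through camera (limma) with a preset correlation of 0.01, adjusted over the lists of 1 comparison. It was run again with the correlation estimated per list, and with fry.

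edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. Further alternatives were TMM scaling, library-sum scaling, TMM with the miR-302 cluster left out, no filter, a minimum of 50, a pseudocount of 10, only the stages compared, a replicate block, the label code as a random block and leaving out each library. Ratios of pooled reads carry 95% exact intervals from the binomial distribution of the reads of both groups. Against a group at 0, a fold is a lower bound set by 3 reads over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

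The steps were tested on simulated counts drawn from the real means and depths of the 299 hairpins, in 10 draws per comparison with 60 hairpins changed per draw. For KO versus WT at E7.5, limma recovered 1.0%, 10.5% and 25.0% of 2-, 4- and 8-fold changes. At E8.5 it recovered 5.0%, 30.5% and 65.5%, and at E9.5 0.5%, 10.0% and 31.5%. For WT E8.5 versus E7.5 the shares were 0.5%, 13.0% and 38.5%, and for WT E9.5 versus E8.5 1.5%, 5.5% and 36.0%. Between 1 and 10 of 2390 unchanged hairpins were called per comparison. edgeR recovered 49.0% to 77.5% of 8-fold changes, with 6 to 12 false calls. In the E8.5 KO simulation, camera called a let-7 list raised 4-fold in 10 of 10 draws and 1 of 140 other list tests. Hairpins were drawn independently there, whereas the correlation estimated for let-7 in the real data was 0.848. The simulation therefore does not give the false calls of the preset correlation in such lists. Positions are on GRCm38 (mm10) from GENCODE M21, in which 284 of the 299 hairpins were found.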

Results

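Small RNA reads were counted per microRNA hairpin in WT and miR-302 KO mouse embryos. E7.5 had 2 WT and 2 KO whole-embryo libraries. E8.5 had 3 WT and 4 KO libraries of Wnt1-Cre sorted cells. E9.5 had 2 WT and 2 KO libraries of Sox10 sorted cells. The WT libraries held 133638 and 190416 reads at E7.5, 24465, 124775 and 179772 at E8.5, and 323389 and 136665 at E9.5. The KO libraries held 24084 and 52362 reads at E7.5, 25611, 46082, 1706 and 9757 at E8.5, and 39667 and 24184 at E9.5. Hairpin names omit the prefix mmu-. Values are normalized counts, given as mean ± SD with n libraries. Errors of log2 fold changes are standard errors (SE), and adjusted p-values are limma's unless another tool is named.

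The targeted cluster of miR-302 and miR-367 lies on chromosome 3 of GRCm38, on the plus strand, within an intron of Larp7, which is transcribed from the minus strand. In order, mir-302b spans 127545228 to 127545301, mir-302c 127545363 to 127545430, mir-302a 127545496 to 127545564, mir-302d 127545624 to 127545689 and mir-367 127545733 to 127545807. The cluster is known for its expression in pluripotent cells and the early embryo. In E7.5 WT embryos miR-302a to miR-302d summed to 4001 and 14226 normalized counts (mean 9113 ± 7230, n = 2). In the E7.5 KO libraries they summed to 13.2 and 31.0 (22.1 ± 12.6, n = 2). In E8.5 WT cells the sum was 5469 ± 1404 (SD, n = 3), against 8.13 ± 8.87 (n = 4, range 0 to 19.3) in KO cells. In E9.5 WT cells it was 338 and 466.3 (402 ± 90.6, n = 2), and the E9.5 KO libraries still held 75.4 and 148 (112 ± 51.4, n = 2). Pooled over libraries, KO kept 0.188% of the WT level at E7.5 (25 reads, 95% exact interval 0.121% to 0.277%) and 0.0862% at E8.5 (11 reads, 0.0430% to 0.154%). At E9.5 it kept 32.6% (127 reads, 27.1% to 38.9%). The KO label of the E9.5 libraries therefore rests on a partial drop of the targeted hairpins, and each E9.5 direction given here carries that limit. mir-367, the last hairpin of the cluster, was not lost: it stood at 69.9 ± 40.8 in WT and 75.2 ± 25.4 in KO at E7.5 (n = 2 each), and at 13.5 ± 4.22 (n = 3) and 18.9 ± 22.4 (n = 4) at E8.5. The latter mean was carried by KO replicate 1 at 50.5, with the other 3 at 0 to 18.7. The fitted log2 fold change was -0.59 ± 1.06 (adjusted p = 0.867). In edgeR and DESeq2 it was 0.51 and 0.70. At E9.5 it was at 1.82 ± 0.0764 in WT (18 reads, n = 2) and at 0 reads in KO, where 3 reads over the group would be 2.92 normalized counts, so a loss was not detectable.

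**Figure D1:**
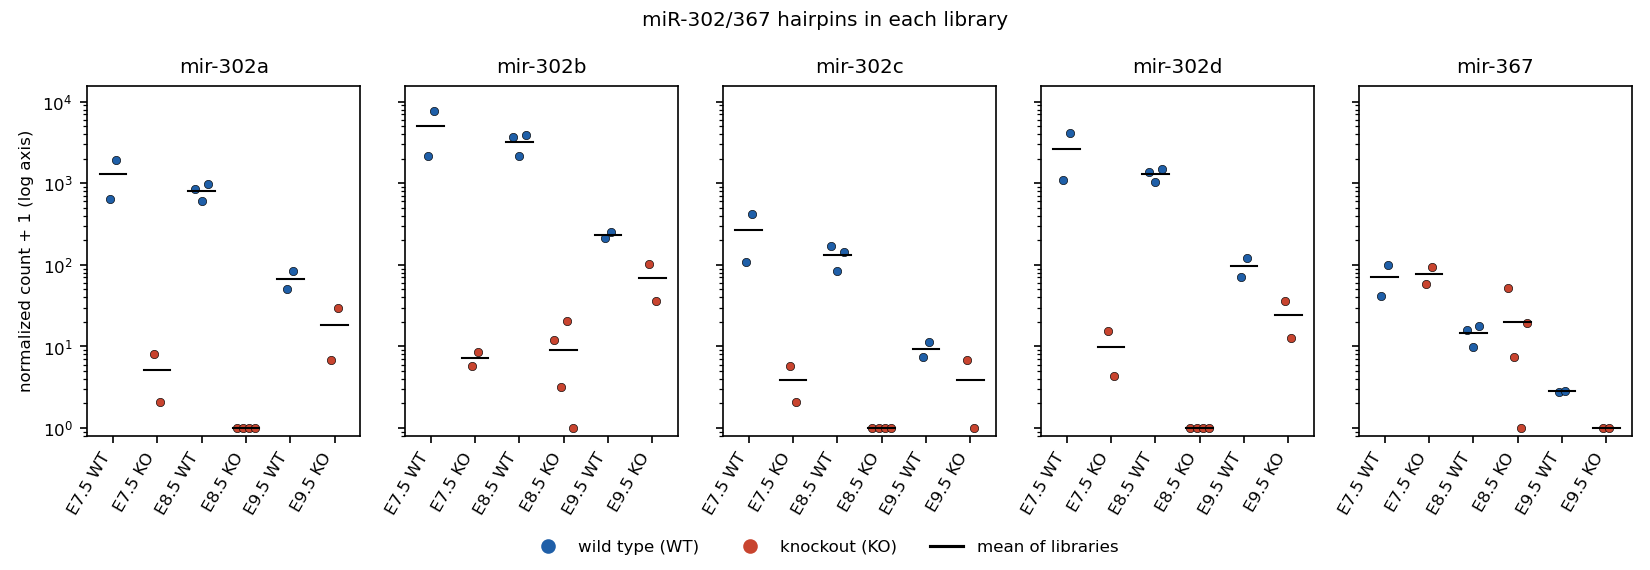
Normalized count + 1 on a log axis for each hairpin of the miR-302 cluster in each of the 15 libraries (points), with the mean of each group (line). mir-302a, mir-302c and mir-302d sit at 0 in all 4 E8.5 KO libraries, whereas mir-302b stands at a mean of 68.0 in the 2 E9.5 KO libraries.

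At E7.5, where the comparison asks what the embryo lacks or gains in microRNAs without miR-302, the 4 miR-302 hairpins fell together. The log2 fold change was -9.18 ± 1.12 (SE) for mir-302b, -8.08 ± 0.88 for mir-302a, -8.03 ± 0.80 for mir-302d and -5.94 ± 1.03 for mir-302c (adjusted p = 1.20e-04, 4.87e-05, 3.14e-05 and 0.00271, n = 2 against 2). The mir-302c ratio rests on 3 KO reads and was 129.5-fold, with an interval of 44.2- to 629-fold. The list of the cluster was lower with 4 of its 5 members, all but mir-367 (4 lower over all hairpins and 4 adjusted over the list alone, camera adjusted p = 3.01e-10, and adjusted p = 0.00767 with an estimated correlation). The miR-290-295 cluster of embryonic stem cells, whose main members share the miR-302 seed, summed to 4599 ± 2185 in WT and 6052 ± 3137 in KO (n = 2 each), and 0 of its 7 members passed over all hairpins or adjusted over the list alone (camera adjusted p = 0.372). Of the 16 tested hairpins of the Sfmbt2 list, which lie in introns of that imprinted gene, 4 fell: mir-297c, mir-297b, mir-297a-3 and mir-297a-4, by -2.79 to -3.13 (adjusted p = 0.00394, 5.32e-04, 0.00211 and 0.00692). In that order they held 53, 54, 67 and 67 reads in E7.5 WT, and 12 reads each in E9.5 WT. They may count the same reads, so they are not 4 independent falls. Those 4 stood at only 11.4 to 14.7 normalized counts in WT, 0 of them passed with edgeR (adjusted p = 0.508 to 0.685), and without KO replicate 1 mir-297c and mir-297a-4 no longer passed (0.0680 and 0.164), nor with no filter (0.0528 and 0.0730), the latter also not without WT replicate 1 (0.0774). As for the list, it did not pass (4 lower adjusted over the list alone, camera adjusted p = 0.0914). The abundant mir-182, of a cluster known from sensory organs, was at 2527 ± 339 in WT and 7855 ± 3713 in KO (log2 fold change 1.56 ± 0.52, adjusted p = 0.204). Its list of 3 did not pass (camera adjusted p = 0.0914), with 0 members past over all hairpins and 1 higher adjusted over the list alone. In total 8 of 299 hairpins were lower in KO and 0 higher, with 28 below an unadjusted p of 0.05, and edgeR and DESeq2 each called 4. With the E7.5 libraries fitted alone the miR-302 fold changes stayed as given but no hairpin passed (limma, 0 of 299, with 16 below an unadjusted p of 0.05). Library-sum scaling, with its smaller effective pseudocount, shifted the median log2 fold change of all hairpins by 0.25 and left 2 calls. The calls of mir-302b (-9.11, adjusted p = 0.0961) and mir-302c (-6.21, 0.258) ended with the 4 of the Sfmbt2 list. Leaving out KO replicate 2 gave 27 calls.

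At E8.5 the neural crest lineage of KO embryos had lost miR-302. mir-302a, mir-302c and mir-302d had 0 reads in all 4 KO libraries, which made them at least 637-, 94.2- and 1017-fold lower than in WT against a floor of 3 reads over the group. mir-302b had 11 KO reads and was 684-fold lower (exact interval 382- to 1370-fold). On the fitted scale the changes were -10.32 ± 0.61 for mir-302d, -9.62 ± 0.67 for mir-302a, -9.22 ± 0.86 for mir-302b and -6.98 ± 0.79 for mir-302c (adjusted p = 4.23e-08, 1.92e-07, 4.56e-06 and 3.62e-05, n = 4 against 3). The miR-302 list fell with them (4 of 5 over all hairpins and 4 adjusted over the list alone, camera adjusted p = 6.33e-14, and adjusted p = 0.00221 with an estimated correlation). Outside the cluster, mir-1953 rose from 0.736 ± 0.868 to 32.4 ± 32.0 (log2 fold change 3.86 ± 0.81, adjusted p = 0.0154, edgeR 0.0299), higher in 4 of 4 KO libraries, but not past the threshold without WT replicate 1 (0.1397) or 3 (0.0892), or under library-sum scaling (0.0695). The KO mean leaned on replicate 3, where 4 reads made 77.3, with 9.29 to 33.6 in the other 3. mir-3081 rose from 0.339 ± 0.587 to 9.23 ± 7.56 (2.71 ± 0.49, adjusted p = 0.00481, edgeR 0.229). In replicate 3 its value of 19.3 was 1 read, with 3.15 to 10.7 in the other 3. Neither passed with no filter (adjusted p = 0.0971 for mir-1953 and 0.120 for mir-3081), with a pseudocount of 10 (0.0753 for both) or in a fit of the E8.5 libraries alone (0.197 for both). Of the 40 tested members of the Dlk1-Dio3 list, named for that imprinted region, 33 were below 0, with a median log2 fold change of -0.83. Of the 40, 0 passed over all hairpins or adjusted over the list alone. The list's camera adjusted p was 0.0162, and adjusted p = 0.801 with an estimated correlation, or 0.196 without KO replicate 4. The direction was not shared by the list's part of the library, 11.6%, 11.0%, 11.96% and 7.43% in KO against 10.3%, 9.80% and 9.70% in WT, which was higher in 3 of 4 KO libraries. mir-541 stood at 739 ± 156 in WT and 540 ± 193 in KO, and mir-379 at 369 ± 106 and 229 ± 105. The let-7 family, which is held back by Lin28 in early cells, summed to 554 ± 40.1 in WT (n = 3) and 749 ± 826 in KO (n = 4), with 0 of 12 members past over all hairpins or adjusted over the list alone (camera adjusted p = 0.320). Its mean was higher in KO while the median log2 fold change was -1.39, since the KO libraries split. The sum was 1645 and 1257 in KO replicates 1 and 4, but 55.7 and 38.7 in replicates 2 and 3, which share a label code. mir-99b was at 65.3 ± 9.08 in WT and 170 ± 49.5 in KO (1.33 ± 0.34, adjusted p = 0.0634), in a list of 6 with 0 members past over all hairpins and 1 higher adjusted over the list alone (camera adjusted p = 0.0863). In total limma called 2 higher and 4 lower of 299 hairpins, with 25 below an unadjusted p of 0.05, edgeR called 5 and DESeq2 12. TMM shifted the median of all hairpins by -0.19. The neural, epithelial and vascular lists had camera adjusted p of 0.320, 0.502 and 0.651, and in the neural list the median (-0.13) and the mean (0.10) differed in sign.

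At E9.5, where the KO label rests on a partial drop of miR-302, the let-7 list was higher in the KO libraries. Its 12 members summed to 1429 ± 848 in WT and 11006 ± 4220 in KO (n = 2 each). let-7c-2 stood at 177 ± 104 and 1717 ± 644 (log2 fold change 3.36 ± 1.94, adjusted p = 0.345) and let-7a-2 at 246 ± 158 and 1462 ± 681 (2.65 ± 1.93, adjusted p = 0.432). All 12 were above 0 with a median of 2.89, but 0 passed over all hairpins or adjusted over the list alone (camera adjusted p = 0.00424, and adjusted p = 0.323 with an estimated correlation). The neural list moved the same way, 338 ± 51.3 against 1358 ± 636 in sum, with 12 of 13 above 0, a median of 2.13, 0 past over all hairpins and 3 adjusted over the list alone (camera adjusted p = 0.00270, and adjusted p = 0.257 with an estimated correlation). Its 13 members include numbered copies that share reads, such as mir-124-1, mir-124-2 and mir-124-3, and are not 13 independent measurements. Within the list the neuronal mir-124-3 was at 22.1 ± 5.85 in WT and 158 ± 88.5 in KO (2.69 ± 0.80, adjusted p = 0.168). The endoderm and liver list summed to 239 ± 123 and 1562 ± 1130, with 5 of 5 above 0, 0 past over all hairpins and 1 adjusted over the list alone (camera adjusted p = 0.0152, and adjusted p = 0.257 with an estimated correlation). In that list the hepatocyte mir-122 was at 56.5 ± 33.1 and 441 ± 345 (2.81 ± 1.44, adjusted p = 0.295), and the list call was lost without WT replicate 1 (adjusted p = 0.0640) or KO replicate 2 (0.0916). The family of miR-99, miR-100 and miR-125 had 6 of 6 above 0, 0 past over all hairpins and 2 adjusted over the list alone (camera adjusted p = 0.0346, and adjusted p = 0.257 with an estimated correlation). That call was lost with TMM scaling (adjusted p = 0.0668), without WT replicate 2 (0.100) and without KO replicate 2 (0.103).

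Other lists were lower in the E9.5 KO libraries. The miR-17-92 clusters, which promote proliferation, had 15 of 15 members below 0 with a median of -0.69 (camera adjusted p = 0.00152, and adjusted p = 0.257 with an estimated correlation), and mir-20a stood at 305 ± 6.88 in WT and 109 ± 11.2 in KO. The Dlk1-Dio3 list had 36 of 40 below 0 with a median of -0.95 (camera adjusted p = 1.77e-05, and adjusted p = 0.257 with an estimated correlation), and mir-379 stood at 189 ± 72.8 and 66.5 ± 24.3. The miR-302 list had 5 of 5 below 0 (camera adjusted p = 0.00668, and adjusted p = 0.257 with an estimated correlation), with mir-302a at -2.17 ± 0.88, mir-302d at -2.13 ± 0.80, mir-302b at -1.94 ± 1.12 and mir-302c at -1.81 ± 1.03 (adjusted p = 0.242, 0.222, 0.345 and 0.345). The list of the miR-322 and miR-503 cluster had 7 of 7 below 0 (camera adjusted p = 0.0497, and adjusted p = 0.257 with an estimated correlation), a call also lost with TMM scaling (0.0596) and without any 1 of 9 libraries, namely the 4 of E7.5, KO replicates 1 and 4 of E8.5, both WT of E9.5 and KO replicate 2 of E9.5 (0.0509 to 0.155, the last without E9.5 KO replicate 2). In these 4 lists 0 members passed over all hairpins or adjusted over the list alone. The miR-290-295 list had 6 of 7 below 0, 0 past over all hairpins and 2 adjusted over the list alone (camera adjusted p = 0.0346, and adjusted p = 0.299 with an estimated correlation). It was lost with TMM scaling (0.0835) and without KO replicate 2 (0.196). The mesenchymal list, which holds miR-199a, miR-199b, miR-214 and miR-140, summed to 1705 ± 105 in WT and 711 ± 50.1 in KO but did not pass (median -1.36, camera adjusted p = 0.169), nor did the Hox-cluster (median 2.25, 0.0733), vascular (1.78, 0.0733), epithelial (1.31, 0.109), miR-182 cluster (1.47, 0.0715) and Sfmbt2 (-0.49, 0.0638) lists. Of these 6 lists, epithelial had 1 member past over all hairpins and 1 adjusted over the list alone, miR-182 cluster had 0 and 2, and the others had 0 and 0. The Sfmbt2 median was 0.04 once the 10 members at or under the floor in both groups were left out. Single hairpins past the threshold were mir-871, at 7.34 and 31.9 in KO (16 reads) against 0 in WT and so at least 52.0-fold higher (adjusted p = 0.00408, edgeR 0.0115), and mir-200c, a repressor of the Zeb factors, at 44.6 ± 17.9 against 3.96 ± 1.02 (3.16 ± 0.56, adjusted p = 0.00992, edgeR 0.141). TMM ended the mir-200c call (2.52, adjusted p = 0.240, or 2.66 and 0.1404 with miR-302 left out), as did leaving out WT replicate 1 (2.95, 0.1405) or KO replicate 1 (2.75, 0.0578), and mir-871 no longer passed without WT replicate 1 (0.0651). The hairpin mir-6236 took 11.4% (95% exact interval 11.1% to 11.7%) and 12.7% (12.3% to 13.1%) of the reads of the E9.5 KO libraries and 0.660% to 4.33% of the others, but did not pass (log2 fold change 2.83 ± 0.74, adjusted p = 0.168). mir-92a-1 took 23.6% (23.2% to 24.1%) and 16.04% (15.6% to 16.5%) in KO against 37.5% (37.3% to 37.6%) and 32.8% (32.6% to 33.1%) in WT, intervals that cover counting error only. It did not pass in normalized counts (log2 fold change -0.34 ± 0.68, adjusted p = 0.801). limma called 2 higher and 0 lower, with 51 below an unadjusted p of 0.05, edgeR 1 and DESeq2 17, and the count was 0 without WT replicate 1 (29 below an unadjusted p of 0.05), 4 without KO replicate 1 and 0 in a fit of the E9.5 libraries alone (92 below). Scaling shifted all hairpins here, by -0.49 (TMM) and -0.45 (library sum) in median log2 fold change. Library-sum scaling, with its smaller effective pseudocount, gave 2 higher and 7 lower.

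Whether the KO effect differed between stages was tested directly, and 7 of 299 hairpins passed (limma F test, 36 below an unadjusted p of 0.05, edgeR 4). The 3 with a mean of at least 100 were mir-302d, mir-302a and mir-302b (adjusted p = 0.00156, 0.00592 and 0.0158), whose log2 fold changes of -8.03 to -9.18 at E7.5 and -9.22 to -10.32 at E8.5 stood against -1.94 to -2.17 at E9.5. In edgeR they had adjusted p of 2.53e-04, 5.31e-04 and 2.53e-04. Their E9.5 WT means of 95.8, 65.8 and 232 limit how far they can fall on the fitted scale, so part of the F test's difference reflects that level. The pooled share of miR-302a to miR-302d left in KO is not bound by that scale, at 0.188%, 0.0862% and 32.6% for E7.5, E8.5 and E9.5. The count was 25 without E7.5 KO replicate 2 and 4 without E7.5 WT replicate 2 or E9.5 KO replicate 1. mir-302b did not pass without E9.5 WT replicate 1 (0.0777), E9.5 WT replicate 2 (0.0737) or E9.5 KO replicate 1 (0.0920), nor under library-sum scaling (0.348) or TMM with the miR-302 cluster left out (0.0521). For the lists no difference between stages was tested.

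In WT, the step from whole E7.5 embryos to sorted E8.5 cells showed which microRNAs accompany the change of stage and source. All 7 members of miR-290-295 were lower over all hairpins and 7 adjusted over the list alone, from 4599 ± 2185 (n = 2) to 294 ± 61.1 (n = 3) in sum, with mir-292a at -4.25 ± 0.75, mir-294 at -4.24 ± 0.80, mir-295 at -4.00 ± 0.67 and mir-291b at -3.80 ± 1.22 (adjusted p = 8.94e-04, 0.00132, 5.66e-04 and 0.0443). Camera gave the list an adjusted p of 6.95e-04, and adjusted p = 0.295 with an estimated correlation. All 16 Sfmbt2 members fell over all hairpins and 16 adjusted over the list alone, from 1511 ± 121 to 26.1 ± 5.18 in sum, with a median of -3.96, or -4.76 with 4 members at 0 set to their bound. They lie between 10467790 and 10517164 on chromosome 2, in introns of Sfmbt2 (10370510 to 10595253), among them mir-669c (-6.35 ± 1.13, adjusted p = 8.94e-04), mir-467e (-5.56 ± 0.80, 1.38e-04) and mir-467c (-4.96 ± 1.01, 0.00244). The list's camera adjusted p was 3.99e-13, and adjusted p = 0.00502 with an estimated correlation. The 3 Hox-cluster members fell, mir-10b by -6.45 ± 1.25, mir-196b by -6.07 ± 0.89 and mir-10a by -5.83 ± 1.36 (adjusted p = 0.00170, 1.59e-04 and 0.00578), 3 over all hairpins and 3 adjusted over the list alone, with a camera adjusted p of 0.0152, and adjusted p = 0.295 with an estimated correlation. let-7 dropped as a list from 8179 ± 6943 to 554 ± 40.1 in sum, with 12 of 12 below 0, 2 lower over all hairpins and 3 adjusted over the list alone. Its camera adjusted p was 0.0329, and adjusted p = 0.801 with an estimated correlation, and the call was lost without E7.5 WT replicate 1 (0.394) and, narrowly, without any 1 of the 4 KO libraries of E7.5 and E9.5 (0.0506 to 0.0509).

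Fewer microRNAs were higher at E8.5. mir-335, which lies in the imprinted gene Mest, rose from 128 ± 68.5 to 1202 ± 75.3 (3.33 ± 0.68, adjusted p = 0.00249), although without E7.5 WT replicate 1 it no longer passed (2.76, adjusted p = 0.0539). mir-92b rose from 148 ± 65.6 to 828 ± 43.5 (2.54 ± 0.82, adjusted p = 0.0443) and mir-674 from 49.6 ± 3.38 to 181 ± 29.2 (1.83 ± 0.50, adjusted p = 0.0179). mir-219a-2, a neural hairpin, had 0 reads at E7.5 and 19.4 ± 4.70 at E8.5, at least 28.8-fold higher (adjusted p = 0.00521, or 0.0539 without E7.5 WT replicate 1 and 0.0551 with a pseudocount of 10). The mir-674 call ended without E7.5 WT replicate 1 (1.90) or 2 (1.77) or E8.5 WT replicate 1 (1.81) or 2 (1.73). The miR-17-92 list rose with 14 of 15 members above 0 and a median of 1.11, from 10756 ± 1809 to 18427 ± 378 in sum, 0 past over all hairpins or adjusted over the list alone (camera adjusted p = 1.59e-05, and adjusted p = 0.295 with an estimated correlation). The neural list was higher relative to other hairpins, with a median of 0.09, 1 member past over all hairpins and 1 adjusted over the list alone (camera adjusted p = 0.00761, and adjusted p = 0.372 with an estimated correlation). The miR-302 hairpins themselves did not pass: mir-302a to mir-302d had log2 fold changes of -0.39 to -0.75 (adjusted p = 0.605 to 0.920), and mir-302a and mir-302b turned positive under TMM (0.06 and 0.18) and library-sum scaling (0.15 and 0.26), as did all 4 without E7.5 WT replicate 2 (0.23 to 0.54). mir-367 was at -2.21 (adjusted p = 0.290, edgeR 0.0788), although DESeq2 called it lower (-2.25, adjusted p = 0.0203). In total 4 hairpins were higher and 51 lower, with 87 below an unadjusted p of 0.05, and edgeR called 15 higher and 64 lower, 51 of them shared with limma. TMM and library-sum scaling shifted the median by 0.53 and 0.59 and gave 9 higher with 38 lower, and 10 with 25. Library-sum scaling also made the effective pseudocount smaller. It ended the calls of mir-10b (-6.35), mir-10a (-7.07), mir-669c (-5.89), mir-467c (-4.57), mir-292a (-3.62) and mir-291b (-3.32), with fold changes as given in parentheses. TMM ended that of mir-291b as well (-3.27, adjusted p = 0.0923). The count was 34 without E7.5 WT replicate 1, where mir-10b (-4.84) and mir-10a (-5.83) no longer passed. mir-92b and mir-291b stood close to the threshold and were lost when any 1 of the 5 libraries compared was left out, with no filter (0.118 and 0.0813) and in a fit of these stages alone (0.0795 and 0.0653). In the authors' deposited cluster table, 1 of 7 clusters held 155 of 413 miRNAs, all with their highest WT mean at E7.5, and 48 of the 51 lower hairpins belonged to it. Hairpins that fall from E7.5 would be placed in such a cluster, so the overlap is not independent support.

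**Figure D2:**
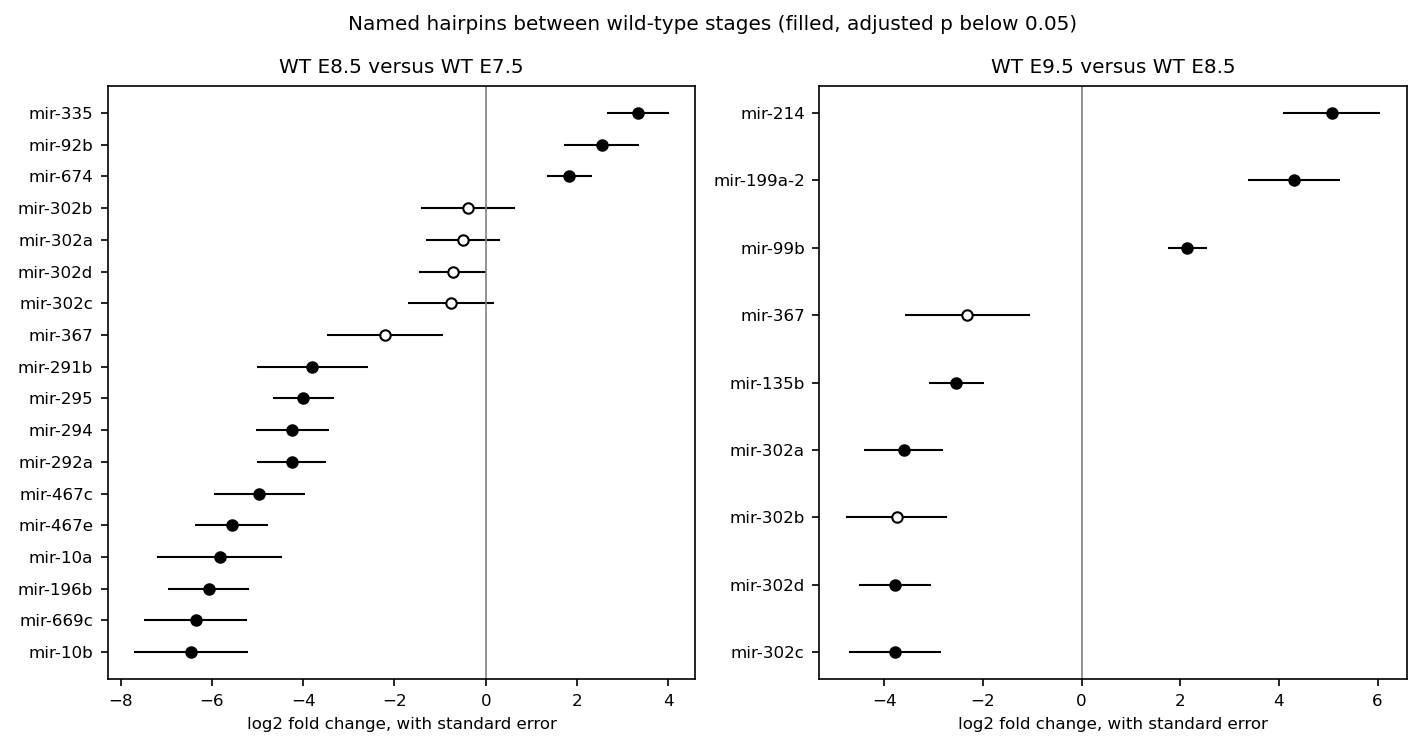
Log2 fold changes (points) with standard errors (bars) of the named hairpins between WT stages, filled where limma's adjusted p was below 0.05. On the left all 5 hairpins of the miR-302 cluster lie below 0, with mir-302b at -0.39. TMM and library-sum scaling, which turned mir-302a and mir-302b positive, are not drawn. On the right mir-214 stands highest at 5.07 and mir-302c lowest at -3.78.

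From E8.5 to E9.5 in WT, miR-302 dropped in the neural crest fractions. mir-302c changed by -3.78 ± 0.94, mir-302d by -3.78 ± 0.73 and mir-302a by -3.61 ± 0.80 (adjusted p = 0.0439, 0.0121 and 0.0231, n = 2 against 3), and mir-302b stood at -3.75 ± 1.02 (adjusted p = 0.0658, edgeR 0.00370). mir-367 was at -2.32 (adjusted p = 0.418), although edgeR (-2.90, adjusted p = 0.0379) and DESeq2 (-2.87, 0.0102) called it lower. The list fell with 3 lower over all hairpins and 4 adjusted over the list alone (camera adjusted p = 4.41e-06, and adjusted p = 0.0576 with an estimated correlation). The mesenchymal mir-214 and mir-199a-2, which lie on chromosome 1 in a transcript antisense to Dnm3, rose: mir-214 from 3.01 ± 0.681 to 132.4 ± 1.49 (5.07 ± 0.99, adjusted p = 0.0121) and mir-199a-2 from 28.0 ± 10.3 to 544 ± 48.6 (4.30 ± 0.93, adjusted p = 0.0231). Reads given to mir-199a-2 may also come from its copy mir-199a-1 on chromosome 9. The mesenchymal list had 5 of 5 above 0, 2 past over all hairpins and 4 adjusted over the list alone (camera adjusted p = 5.62e-05, and adjusted p = 0.172 with an estimated correlation). mir-99b rose from 65.3 ± 9.08 to 298 ± 95.01 (2.14 ± 0.40, adjusted p = 0.0121), and its list of 6 had 6 above 0, 1 past over all hairpins and 1 adjusted over the list alone (camera adjusted p = 0.00278, and adjusted p = 0.198 with an estimated correlation). The epithelial list fell, 254 ± 32.8 to 28.0 ± 1.502 in sum, with 7 of 7 below 0, 1 past over all hairpins and 3 adjusted over the list alone (camera adjusted p = 1.61e-04, and adjusted p = 0.1104 with an estimated correlation), and in it mir-200c changed by -3.70 ± 0.51 (adjusted p = 0.00148). miR-290-295 fell further, to 42.9 ± 9.54 in sum, with 7 of 7 below 0, 0 past over all hairpins and 5 adjusted over the list alone (camera adjusted p = 2.20e-05, and adjusted p = 0.172 with an estimated correlation). The Dlk1-Dio3 list had 40 of 40 below 0 with a median of -1.02 and 0 past over all hairpins or adjusted over the list alone (camera adjusted p = 4.37e-07, and adjusted p = 0.198 with an estimated correlation). mir-135b changed by -2.55 ± 0.56, from 180 ± 43.8 to 31.2 ± 14.5 (adjusted p = 0.0231). mir-5110 rose as well, by 3.01 ± 0.72 (adjusted p = 0.0348). let-7 did not pass (12 of 12 above 0, median 1.27, camera adjusted p = 0.0911). In total limma called 4 higher and 5 lower, with 43 below an unadjusted p of 0.05, and edgeR called 12 higher and 18 lower, all 9 limma calls among them. Library-sum scaling, with its smaller effective pseudocount, gave 7 higher and 4 lower, without mir-214 (5.44), mir-5110 (5.42), mir-302a (-3.65) and mir-302c (-3.95). No filter ended the calls of mir-135b, mir-199a-2, mir-302a, mir-302c and mir-5110 (adjusted p = 0.0694 to 0.180). Leaving out any 1 of the 5 WT libraries compared left 1 call, mir-200c, with adjusted p of 0.0507 to 0.309 for the other 8, and leaving out E8.5 KO replicate 3, which enters only through the shared spread, gave 19.

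**Figure D3:**
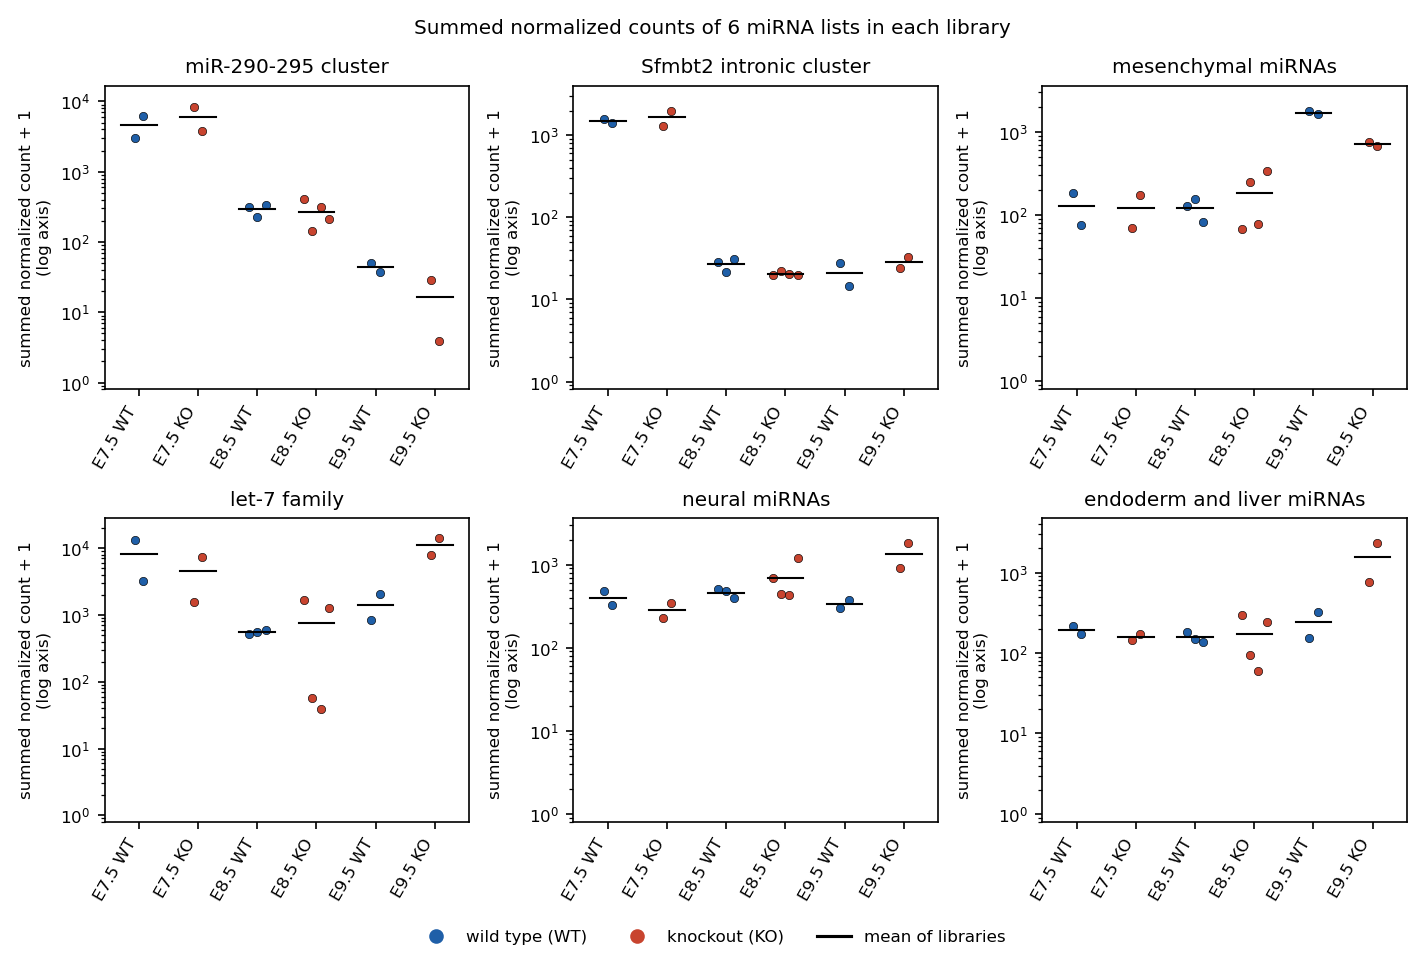
Summed normalized counts + 1 of 6 lists on a log axis in each of the 15 libraries (points), with group means (lines). The miR-290-295 sum fell from a WT mean of 4599 at E7.5 to 42.9 at E9.5, and the let-7 sum stood at 1429 in E9.5 WT and 11006 in E9.5 KO.

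Lists of other cell types too small for a test were given as levels. mir-1a-1, the only tested member of the striated muscle list, was at 17.2 ± 9.08 in E8.5 WT and 18.7 ± 29.7 in E8.5 KO, where replicate 1 held 63.1 and the other libraries 0 to 7.46. mir-34a, the only tested member of its family, was at 2.92 ± 2.73 and 13.9 ± 8.30 in these groups. No blood hairpin passed the filter.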

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

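The tests of the WT level, of carry-over, of mixing, of the share of sorted cells, of the label codes, of depth for single hairpins and of other splits without miR-302 were chosen only after the results they address were seen. The tests of depth for the lists and of the other splits with all hairpins were not.

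The total of the muscle list, carried by mir-1a-1 alone, was 63.1 normalized counts in E8.5 KO replicate 1, far from the 0 to 7.46 of the other 3 libraries of its group. It was the only 1 of 22 items examined in that group to stand apart so far, where chance gives about 1 in 20. For 7 hairpins the KO effect differed between stages, with which the cell source changed, since limma's interaction F test passed. These were mir-302d (adjusted p = 0.00156), mir-302a (0.00592) and mir-302b (0.0158), which fell less at E9.5, mir-871 (0.00997), mir-200c (0.0158), mir-297b (0.0158) and mir-297a-3 (0.0476). The log2 fold changes of KO versus WT at E7.5, E8.5 and E9.5 were -0.95, 0 and 4.05 for mir-871 and -1.30, 0.20 and 3.16 for mir-200c. mir-297b and mir-297a-3 had -3.12 and -3.13 at E7.5, no reads at E8.5 and at most 0.882 normalized counts on average at E9.5, so little was left to fall. edgeR called the interaction for the 3 miR-302 hairpins and mir-871 (0.0228), but not for mir-200c (0.0591), mir-297b (0.986) or mir-297a-3 (0.968), and these 3 did not pass under TMM with the miR-302 cluster left out either (0.0521 to 0.126).

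The E9.5 KO libraries held 127 reads of miR-302a to miR-302d, 32.6% of the WT level, against 0.188% at E7.5 and 0.0862% at E8.5. A WT level too low for a loss to be seen was argued against, since the upper bound of the share left at E8.5 would allow 0.600 of these 127 reads. Carry-over from the E7.5 WT libraries was argued against as well: it would have brought 43.6 and 11.2 reads of miR-290-295 into the 2 libraries, which held 19 and 1, 20 in all (one-sided exact Poisson p = 2.30e-05 and 1.62e-04). Mixing with E9.5 WT cells stays open, because shares of 31.8% and 16.2% would be needed and 0% of 64 abundant hairpins lay below the level that this requires, but 0% did so in the E7.5 KO libraries too, so the test had no reach. Incomplete deletion, carry-over from the E8.5 WT libraries, the stage and the label code were not tested here and stay open.

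In the E9.5 KO libraries 4 lists were higher and 5 lower than in WT with camera at its preset correlation, of which 6 passed under TMM, whereas 0 of the 15 lists passed with an estimated correlation (1 below an unadjusted p of 0.05) and 0 with fry (7 below), so the pattern rests on that setting. Lower depth of the KO libraries was argued against for 5 of these lists: with WT thinned to 24184 reads the let-7 median was 2.91 (2.79 to 3.17 over 20 draws, against 2.89), and the neural, endoderm and liver, Dlk1-Dio3 and miR-17-92 medians were 2.01, 2.59, -0.93 and -0.77. A lower share of the Sox10 sorted cells stays open: the means of the epithelial, neural, vascular, and endoderm and liver lists stood at 1.26 ± 0.63 (SE), 1.75 ± 0.61, 1.90 ± 0.79 and 2.58 ± 1.17, with a largest gap of 1.32 ± 1.07, but the mesenchymal list at -1.06 ± 1.10 widened it to 3.63 ± 1.30, which would argue against that share only if this list, with 1705 normalized counts in E9.5 WT, marked cells other than the sorted ones. A batch marked by the label code cannot be told apart from the genotype, because 0 codes were shared by WT and KO at E9.5. The loss of miR-302 itself stays open and untested as an explanation.

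Outside miR-302, 8 hairpins passed in KO versus WT: mir-297a-3, mir-297a-4, mir-297b and mir-297c at E7.5, mir-1953 and mir-3081 at E8.5, and mir-871 and mir-200c at E9.5. The 4 at E7.5 may count the same reads and are not 4 independent calls. With WT thinned to the median KO depth, the 4 at E7.5 all passed in the median of 20 draws. Thinning leaves their 1 or 2 KO reads as they were, and edgeR, which takes depth into account, gave adjusted p of 0.508 to 0.685. Lower depth of the KO libraries therefore stays open for these 4. For mir-1953 and mir-871, edgeR called both (adjusted p = 0.0299 and 0.0115), but that criterion was set after the results were seen. Thinning could not test them, since their WT levels of 0.736 and 0 lay under the floors of 1.27 and 2.92. KO held more reads of each than WT (32 against 7 and 16 against 0), yet depth was not settled for either. Of mir-200c and mir-3081, 2 passed in the median after thinning. The mir-3081 WT level of 0.339 was under the 1.27 of 3 reads over the KO group, which leaves little to thin. For mir-200c the WT level of 3.96 stood above that floor (2.92), and the call stayed in 15 of 20 draws. Depth stays open for both, since edgeR called neither (0.141 and 0.229). At E8.5 the real grouping gave 6 calls and the highest of the other splits 1, so that 1 of 35 splits, the real one, reached 6. That is the lowest share these splits can give, and miR-302, the deleted cluster, makes up 4 of the 6 calls. Without its hairpins the real grouping gave 2 calls and the highest other split 1 (1 of 35 reached 2). In simulation limma made 10 false calls in 10 draws at E8.5, so chance is not excluded for these 2 calls. Sparse reads stay open as a candidate explanation for mir-3081, with 19 KO reads, and for the 4 at E7.5, with 1 or 2 KO reads each, none of which edgeR called. The mir-200c call uses the same E9.5 WT libraries (3.96 ± 1.02) as its drop from E8.5 to E9.5 in WT, so these are not independent, and no biological explanation was tested.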

How the results depend on the processing

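Averaging numbered copies, leaving out E7.5 KO replicate 1 and E8.5 KO replicate 3 together, a minimum of 10 reads and the crossed pairing were tests chosen only after the data were seen. No result reversed its direction past the threshold. Of the values of named hairpins under settings other than leaving out 1 library, 497 kept direction and side of the threshold, 36 no longer passed, 8 newly passed and 10 changed sign without passing. With 1 library left out these numbers were 553, 68, 2 and 7.

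The counts of calls were 8 (KO versus WT at E7.5), 6 (E8.5), 2 (E9.5), 55 (WT E8.5 versus E7.5), 9 (WT E9.5 versus E8.5) and 7 (KO effect between stages). Counts within 1.5 times of these are not listed here. TMM gave 1 at E9.5, as did TMM with miR-302 left out, which also gave 3 between stages and shifted the median log2 fold change by 0.21 at E7.5, -0.38 at E9.5 and 0.48 from WT E7.5 to E8.5. Library-sum scaling, which also made the effective pseudocount smaller, gave 2 at E7.5, 9 at E9.5 and 35 from WT E7.5 to E8.5. No filter gave 18 at E7.5, 8 at E9.5, 4 from WT E8.5 to E9.5 and 12 between stages, and a minimum of 50, which tests fewer hairpins, gave 4 at E7.5, 1 at E9.5 and 35 from WT E7.5 to E8.5. A pseudocount of 10 gave 10 at E9.5, 17 from WT E8.5 to E9.5 and 12 between stages. Only the stages compared gave limma counts of 0 at E7.5 (16 below an unadjusted p of 0.05), 0 at E9.5 (92 below) and 18 from WT E8.5 to E9.5; fewer libraries then share the estimate of the spread. edgeR gave 4 at E7.5, 1 at E9.5, 30 from WT E8.5 to E9.5 and 4 between stages. DESeq2 gave 4 at E7.5, 12 at E8.5 (8 higher), 17 at E9.5, 91 from WT E7.5 to E8.5 and 40 from WT E8.5 to E9.5. Without E7.5 KO replicate 1 and E8.5 KO replicate 3 together the counts were 5 at E7.5 and 21 from WT E8.5 to E9.5. The label code as a random block (correlation 0.00959) left each of these counts as it was. It could not show a code effect at E7.5, where all libraries shared the same code, or at E9.5, where the code followed the genotype. Except where noted, the cause was not tested.

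With 1 library left out, the count ran from 6 (without E7.5 KO replicate 1) to 27 (without E7.5 KO replicate 2) at E7.5, from 5 to 7 at E8.5, and from 0 (without E9.5 WT replicate 1, limma, 29 below an unadjusted p of 0.05) to 4 (without E9.5 KO replicate 1) at E9.5. It ran from 34 (without E7.5 WT replicate 1) to 72 (without E8.5 KO replicate 3) from WT E7.5 to E8.5, from 1 (without any 1 of the 5 WT libraries compared) to 19 (without E8.5 KO replicate 3) from WT E8.5 to E9.5, and from 4 (without E7.5 WT replicate 2 or E9.5 KO replicate 1) to 25 (without E7.5 KO replicate 2) between stages. A lone library left in a group was assumed to vary like the other groups.

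Replicate numbers did not pair the samples: deviations of same-numbered WT and KO libraries correlated at -0.229 at E7.5, 0.143, 0.128 and 0.0904 at E8.5 and 0.191 at E9.5. The replicate block gave 9 at E7.5, 5 at E8.5, 0 at E9.5 (limma, 48 below an unadjusted p of 0.05), 48 from WT E7.5 to E8.5, 1 from WT E8.5 to E9.5 and 1 between stages (mir-302b, with mir-302a and mir-302d at 0.0707). Crossing the numbers at E7.5 gave 8.

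Of 75 list tests, 24 passed with camera, 3 of them with an estimated correlation, 21 with TMM and 21 (without E9.5 KO replicate 2) to 27 (without E8.5 KO replicate 3) with 1 library left out. fry gave 10, 9 of them shared.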

Other observations

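The tests of whether the chromosome X hairpins fall together and of a doubling of their reads were chosen only after their values were seen, and the test of the median of the cluster in E9.5 KO was not.

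On chromosome X of GRCm38, 7 hairpins of 5 families (mir-465b, mir-465c, mir-470, mir-871 and mir-878) lie between 66801508 and 66835842, between Slitrk2 (66649318 to 66661393) and Fmr1 (68678541 to 68717963), with no annotated gene over them. All 5 families were lower in E8.5 WT than in E7.5 WT, against 40 of 266 other families (Fisher's exact test, two-sided p = 1.04e-04). mir-465c-1 stood at 49.4 ± 15.5 normalized counts at E7.5 (n = 2) and at 0 reads at E8.5 (n = 3), at least 126.3-fold lower. The cluster was picked because its hairpins had been seen to fall, so this p restates the pattern and decides nothing, and stage and cell source changed together. mir-871 was higher in E9.5 KO, whereas the other 4 families had 0 reads in both E9.5 KO libraries and a median log2 fold change of -0.93. No rise of the cluster as a whole was seen. A doubling of their 34 WT reads would have given 6.97 KO reads (one-sided exact binomial p = 0.00176). That test takes reads as independent, whereas the E9.5 WT replicates differed beyond sampling noise (chi-square per degree of freedom 49.7). mir-465b-1 and mir-465c-1 held 11 and 12 of the WT reads, which they may share, and mir-878 was at 0 in the lower of its 2 WT libraries. A rise is therefore not excluded. For each family alone a fall was not measurable, because 3 reads over that group would be 2.92 normalized counts, above its WT level. A fall of their sum was not tested.

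The 2 E7.5 KO libraries differed in their most abundant hairpins. mir-182 took 18.3% (95% exact interval 17.8% to 18.8%) of the reads in replicate 1 and 9.11% (8.87% to 9.36%) in replicate 2, and mir-92a-1 took 1.12% (0.988% to 1.26%) and 9.62% (9.37% to 9.88%). In all 13 other libraries mir-92a-1 took between 9.11% and 37.5%.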
